A study of Mus musculus with 2 samples.

How the data were processed

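Chromatin carrying trimethylated lysine 4 of histone H3 (H3K4me3) was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in intestine of B6NCrl mouse embryos at embryonic day 15.5. The labels give 1 group with 2 biological replicates, each a mixed-sex pool: 78 embryos in replicate 1 and 62 embryos in replicate 2. There was no second condition, so the comparisons were between the replicates, between peaks and annotation, and between gene lists and random genes. No significance test was run, because the files hold peaks without read counts.

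Per the file descriptions deposited with the samples, the 4 peak lists are narrowPeak files on the mouse assembly mm10. 1 list was called on each replicate against a control, 1 on both replicates together (the pooled list), and the last is a replicated list. All 23467 peaks of the replicated list were found with the same values among the 32247 peaks of the pooled list, so these lists were used only as descriptions and never as further replicates. The peak caller, the aligner and the calling thresholds are not given in the sources used here. The enrichment of a peak is the deposited signal value, the number the authors' caller gave it, with no unit stated. The confidence of a peak is the deposited −log10 q-value. The smallest −log10 p in the lists was 2.02, and 3.69% of replicate 1 peaks and 3.82% of replicate 2 peaks had a q-value over 0.05, so the deposited lists reach down to weak peaks. Read depth is unknown, since the files hold no counts. No interval that needs a depth is given, and a gene without a peak was below the caller's threshold and not shown to lack the mark. Input libraries were not analysed here.

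Peak positions were compared with GENCODE M21 on GRCm38, the assembly that mm10 names. All peaks lay within the lengths of the 21 assembled chromosomes, and 14 peaks of replicate 1 and 15 of replicate 2 on other sequences were left out. Overlap meant at least 1 shared base. A protein-coding gene was called marked when both replicates had a peak within 1000 bases of a transcription start site (TSS) of any of its protein-coding transcripts. Such a peak can belong to a neighbouring gene. The signal value of a gene was the highest among those peaks. For widths, peaks of 1 replicate lying 1000 bases apart or less were joined into domains, and the widest domain at a TSS was averaged over both replicates. Errors are the SD over the 2 replicates, which comes from only 2 values. Background came from 100 shuffles of the peaks along their own chromosomes, and for gene calls and far peaks from 20 shuffles.

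The 33 gene lists were fixed before the data were examined, as were the widths, windows and alternatives. Each list's number of marked members and the median width over marked members were set against 10000 random lists of the same size, matched on the decile of the CpG count within 500 bases of the TSS. Widths used random lists of marked genes, and needed at least 3 marked members. A percentile is the share of random lists below the value, ties counted as 0.5. Values at or above the 97.5th or at or below the 2.5th percentile are described as above or below the random range. Chance alone would put at most about 1.65 of 33 lists outside it for marked members, and about 1.4 of the 28 lists with a width. Genes are not independent replicates, and the percentiles describe these libraries. Medians of the signal value by list were added after the files had been examined. Only 1 pair of lists shared a member, Hoxb5. Olfr643 had no protein-coding transcript and was not counted. Ighm and Amy2b, which are not protein-coding in this annotation, were not counted and had no peak at a TSS.

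Genes were named by a rule fixed beforehand: the 25 widest domains, the 10 highest signal values, up to 6 marked members of each list by width and up to 6 unmarked members in list order, the 5 strongest genes marked in 1 replicate only for each replicate, the 10 strongest replicated peaks over 5000 bases from any TSS, and any Hox gene.

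The scripts were tested on simulated peaks. All of 8828 simulated marked genes were called (100%), and 670 further genes were called, each near another simulated peak. Of 200 random null lists, 5 fell outside the 95% range for marked members and 10 for width. Far peaks were also compared with RefSeq transcript starts on the same assembly. The alternatives were other overlap rules, a −log10 q of at least 5, a signal value of at least 5, TSS windows of 500 and 2000 bases, 1 TSS per gene, each replicate left out, the authors' whole-series lists, random lists without matching, other joining gaps, other distances and other sets of TSSs. Matching random lists on the CpG count and on start sites within 5000 bases was added later. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.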

Results

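H3K4me3, a histone mark found at active and CpG-dense promoters, was mapped in embryonic mouse intestine at day 15.5 in 2 pools of embryos. Replicate 1 gave 29330 peaks and replicate 2 gave 29468 peaks, which covered 33.0 and 32.7 Mb on the assembled chromosomes. The median peak was 851 bases wide in replicate 1 and 836 bases in replicate 2. The authors' signal value had a median of 8.60 and 9.08. Read depth is unknown. The series has 1 group, so each result describes this tissue and the spread between its pools. Errors are SDs over both pools (n = 2).

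The pools shared their strong peaks and differed in their weak ones. In replicate 1, 82.6% of the peaks were found in replicate 2, and 83.4% the other way round, against 2.44% and 2.45% for shuffled peaks. The Jaccard index of the covered bases was 0.802. Across 24208 shared peaks, which are not independent replicates, the signal values had a Spearman rho of 0.856. When peaks were ranked by signal value and parted into 5 equal groups, 40.3% of the weakest group of replicate 1 and 41.0% of that of replicate 2 were shared. Each of the strongest 2 groups was shared at 100%. The 5108 peaks of replicate 1 alone had a median signal value of 2.86, and the 4902 of replicate 2 alone one of 2.92, against 14.4 and 15.3 for shared peaks. Of the authors' pooled list, 68.6% of the peaks were found in both replicates and 12.5% in neither. Of the replicated list, 94.1% were found in both.

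**Figure D1:**
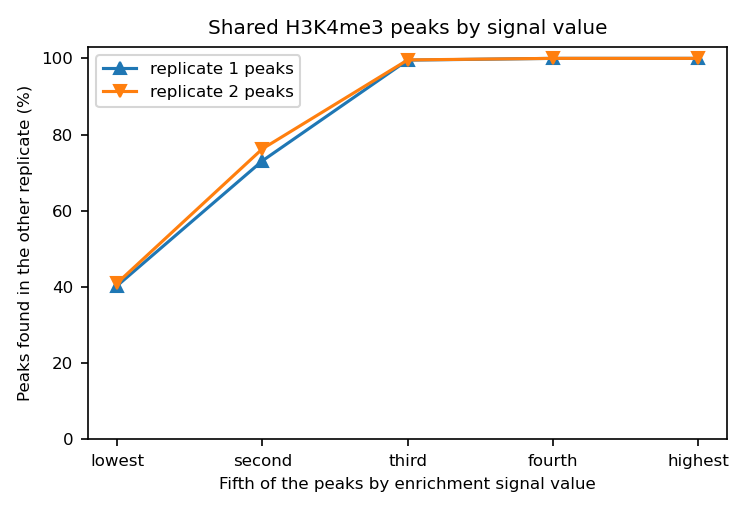
Share of the H3K4me3 peaks of each replicate (percent, y axis) found in the other replicate, for 5 equal groups of peaks ranked by signal value (x axis). Blue upward triangles are replicate 1 peaks and orange downward triangles replicate 2 peaks; the share rises from 40.3% and 41.0% in the weakest group to 100% in the strongest.

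Most peaks lay at promoters. Of the peaks, 66.7% ± 0.0278 (SD, n = 2) were within 1000 bases of an annotated TSS, 20.7% ± 0.0618 lay elsewhere in a gene body and 12.6% ± 0.0896 were intergenic. Shuffled peaks of replicate 1 had 9.16% at a TSS. Peaks over 5000 bases from any TSS made up 15.7% ± 0.0567, against 74.5% of shuffled peaks. These shares moved with the peak threshold: with signal values of at least 5, 85.6% of the peaks lay at a TSS and 8.48% were far from one.

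A peak at the TSS was present in both replicates for 14488 of 21853 protein-coding genes (66.3%), while 7051 had a peak in neither. Replicate 1 marked 14667 genes and replicate 2 marked 14623. Shuffled peaks marked 5.29% of the genes in a replicate. The share of marked genes followed promoter CpG content: 0.869% of the genes in the lowest decile of CpG count, 53.2% in decile 4 and 99.8% in decile 10. Marked genes had a median domain width of 1984 bases and a median signal value of 30.5. Across genes, widths of the replicates had a Spearman rho of 0.914 and signal values one of 0.833.

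The widest domain, at Meis2, a homeobox transcription factor gene, spanned 17539.5 ± 510 bases on chromosome 2, from 116056005 to 116073183 in replicate 1 (GRCm38/mm10). Ptch1, which encodes the hedgehog receptor, had 17514.5 ± 711 bases on chromosome 13, from 63556979 to 63573990. Tbx2 had 15598 ± 31.1, Meis1 14362.5 ± 105, and the domain of Hoxb5 and Hoxb6 14250 ± 413 bases. Foxf1, a transcription factor of gut mesenchyme, had 12596 ± 102 bases, Hand2 12052 ± 666, Nkx2-3 12051 ± 735 and the imprinted growth factor gene Igf2 11957 ± 999.8. The epithelial genes Gata6, Shh and Cdx2 had 10756 ± 1686, 9594.5 ± 332 and 9346 ± 489 bases. The other domains among the 25 widest were at Kdm6b, Zfp503, Tnrc18, Bahcc1, Hoxa2, Setd1b, Lrba with Mab21l2, Hoxa6 with Hoxa3 and Hoxa5, Midn, Thra, Tpm1, Irf2bp2 and Hoxb4. The pools disagreed at some of them: the Hoxa2 domain was 8224 bases in replicate 1 and 14091 in replicate 2. In replicate 1, 1 domain of 13781 bases covered Hoxa3, Hoxa5 and Hoxa6. The replicate 2 domain at Hoxa5 was 6346 bases wide and ended before the 5′ end of Hoxa6.

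The 10 genes with the highest signal values were not among those at the 25 widest domains. The values were 52.4 ± 6.30 at Wtap, a subunit of the RNA methylation complex, 51.6 ± 2.29 at Prrc2a and 51.2 ± 6.96 at Eif4e, which encodes the cap-binding translation factor. Frs2, Syncrip, Smc3, Nploc4, Nkapd1 and the shared promoter of Ears2 and Ubfd1 followed, the last at 50.6 ± 0.754. These values differed by less than most of their SDs and set no order.

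Genes of gut epithelial identity were marked more often and more widely than random genes of like CpG count within 500 bases of the TSS. All 31 genes of the list of epithelial identity were marked, where random lists had a median of 24. Their median domain was 4183.5 bases wide against 1782.5 in random lists, above all 10000, while their median signal value of 16.0 was below the random median of 25.8 and at percentile 0.38. Beside Gata6, Shh and Cdx2, the widest were Foxa1 with 9328 ± 4395 bases, Klf5 with 7324 ± 1766 and Gata4 with 7232 ± 2057. Of 18 stem and progenitor genes, 17 were marked, within the random range, with a median width of 3150 bases (percentile 99.9). They included Myc (6085 ± 65.1 bases), Lrig1 (5526 ± 600) and the Wnt target Axin2 (5356 ± 14.1), and Olfm4 was unmarked.

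Genes of mature enterocytes had weak marks. Of 22, 13 were marked against a random median of 7 (percentile 99.99), with a median signal value of 5.39 against 10.9 in random lists (percentile 1.51). Mttp, needed for lipoprotein assembly, had a signal value of 20.6 ± 5.27 and Fabp1, a fatty acid binding protein gene, one of 3.92 ± 0.242. Among the members with no peak at a TSS in either replicate were the brush border enzyme genes Sis, Lct and Treh and the glucose transporter gene Slc2a2. They were named in list order and do not stand for all enzyme or transporter genes of the list. With signal values of at least 5, only 6 enterocyte genes were marked and the list was within the random range (percentile 61.2). Without matching on CpG content the random median was 15 and the list was also within the range (percentile 23.6).

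Of 19 goblet and Paneth cell genes, 7 were marked, the random median. Against random lists without matching this count was below the range (median 13, percentile 0.5). The median width of the 7 genes, 3278.5 bases, was above the random range. It was led by the Notch ligand genes Dll1 (6288 ± 1119) and Dll4 (5921 ± 1469) and by Gfi1 (6026 ± 6.36). Among the unmarked members were the secretory product genes Tff3, Clca1, Spink4 and Zg16. Of 20 enteroendocrine genes, 12 were marked (percentile 2.56), within the random range but below it at both thresholds. Their domains were narrow, with a median of 1010 bases against 1760.5 (percentile 0.02), and their median signal value was 6.69 against 27.7. Insm1, a transcription factor gene, had 3312 ± 252 bases. Hormone genes went both ways: Cck was marked, at a signal value of 4.69 ± 0.161, and Gcg, Gip and Nts were unmarked. Outside the naming rule, the hormone genes Sct (signal value 18.1 ± 1.20) and Pyy (4.47 ± 2.85) were also marked, and Sst and Ghrl were unmarked. The narrow median was lost when peaks up to 3000 bases apart were joined (percentile 51.6).

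**Figure D2:**
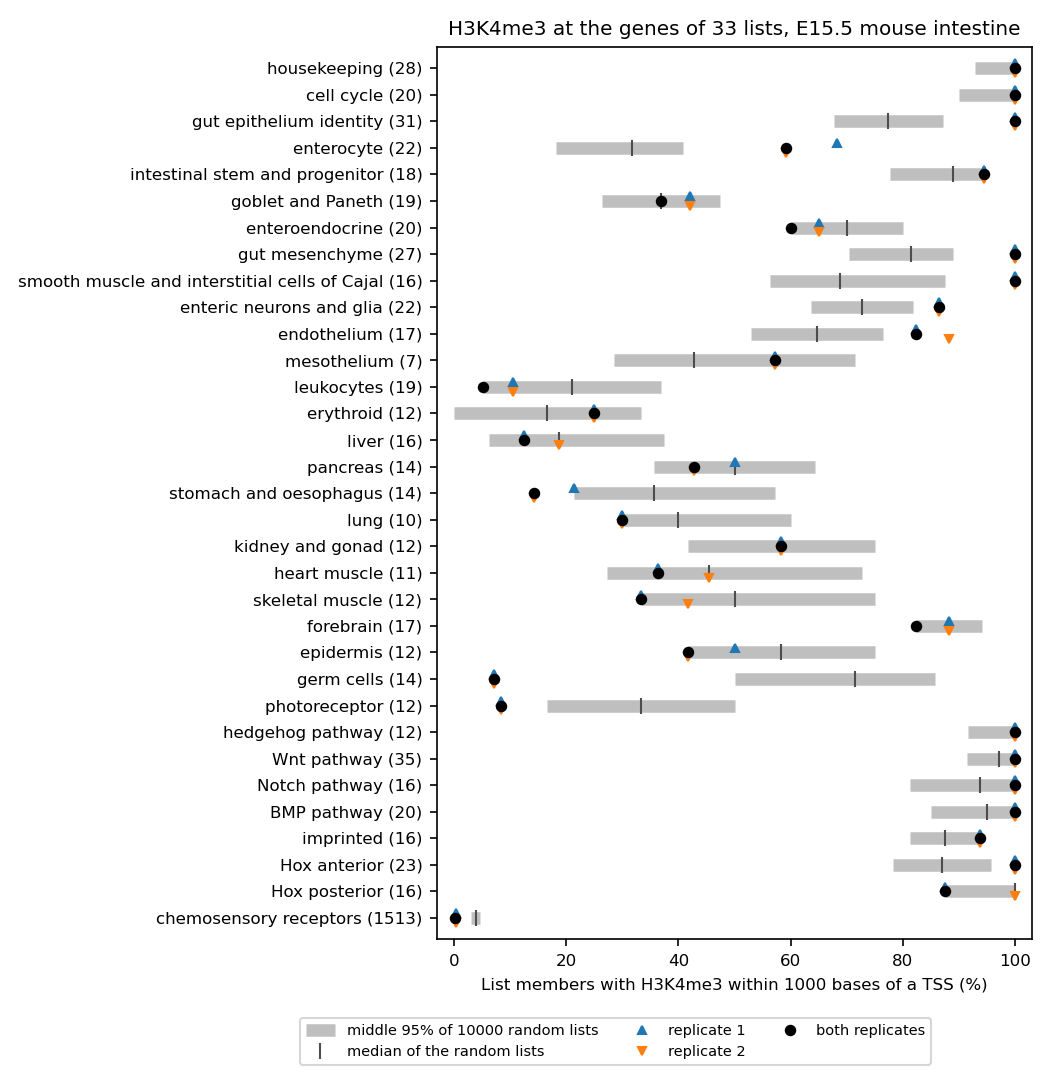
Share of the members of each of 33 gene lists (percent, x axis) with an H3K4me3 peak within 1000 bases of a TSS, with the number of members in brackets. Black circles are genes marked in both replicates, triangles single replicates, grey bars the middle 95% of 10000 random lists matched on CpG content and ticks their medians; all 31 epithelial identity genes and 1 of 14 germ cell genes were marked.

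All 27 genes of gut mesenchyme were marked against a random median of 22, with a median width of 4557.5 bases against 1970.5, above all 10000 random lists. Beside Foxf1 and Nkx2-3, Foxf2 had 9024 ± 1505 bases, Nr2f2 8496 ± 916 and Hlx 8142 ± 124. All 16 genes of smooth muscle and interstitial cells of Cajal, the pacemaker cells of the gut, were marked against a random median of 11. Their median width was 3352 bases against 1545, and their median signal value 12.5 against 19.6, within the random range. Actg2, the smooth muscle gamma actin gene, had 4432 ± 217 bases at a signal value of 4.81 ± 0.577, and Srf had 4189 ± 31.1 bases at 48.2 ± 1.84.

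Of 22 genes of enteric neurons and glia, 19 were marked (percentile 98.7). They included Hand2, Ednrb (4152 ± 245 bases), Phox2b (4150 ± 105 bases) and Tlx2 (3618 ± 344), while Plp1, S100b and Vip were unmarked. The median width was 2990 bases against 1830.5 and the median signal value 8.72 against 27.9, below all random lists. Without joining of peaks, the smooth muscle and enteric neuron lists lay at the 71.9th and 15.7th percentiles of width. With signal values of at least 5, the enteric neuron list had 14 marked genes (percentile 15.1) and the smooth muscle list 13 (percentile 97.48), and the enteric neuron list was also within the random range at a −log10 q of at least 5, with a window of 500 bases, with 1 TSS per gene and in the pooled list. The width call ended for smooth muscle at the signal threshold (percentile 94.8) and for enteric neurons at the q threshold (percentile 69.0).

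Of 17 endothelial genes, 14 were marked (percentile 99.3), among them Kdr, the gene of the VEGF receptor, with 3417 ± 318 bases. With signal values of at least 5, 10 were marked, within the random range, as at a −log10 q of at least 5 (percentile 72.3), with a window of 500 bases (percentile 97.0) and against random lists without matching (percentile 91.8). Of 7 mesothelial genes 4 were marked, with Wt1 at 3764 ± 484 bases. Of 19 leukocyte genes only Spi1 was marked, at a signal value of 2.80 ± 0.828, and Ptprc, Csf1r, Adgre1, Cd68 and Cd3e had no peak at a TSS (percentile 2.44). Leaving out replicate 1 or replicate 2, 2 leukocyte genes were marked, within the random range, as was the list with a window of 500 bases and in the pooled list. Of 12 erythroid genes 3 were marked, Klf1, Gypa and Nfe2, against a random median of 2 (percentile 84.0), and the globin genes Hba-a1, Hba-a2, Hbb-bt and Hbb-bs were unmarked. Without matching, the random median was 8 and the erythroid list was below the range (percentile 0.245).

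Genes of other organs were marked at or below the level of random genes. For stomach and oesophagus 2 of 14 genes were marked, Sox2 and Sox21 (percentile 0.835), for germ cells only Dazl of 14 (below all random lists) and for photoreceptors only Opn1sw of 12 (percentile 0.53). Without replicate 2, the stomach list had 3 marked genes and was within the random range, as was the photoreceptor list with a window of 2000 bases and in the replicated list. Liver had 2 marked of 16, pancreas 6 of 14, lung 3 of 10, kidney and gonad 7 of 12, heart muscle 4 of 11, skeletal muscle 4 of 12, forebrain 14 of 17 and epidermis 5 of 12, all within the random range. Against random lists without matching, the liver list was below all of them, and lung (percentile 1.135) and skeletal muscle (percentile 1.085) were below the range. Alb and Afp of the liver, Sftpc of the lung and Myh6 and Myh7 of heart muscle had no peak at a TSS. Median signal values of marked members were low in forebrain (11.3 against 31.7), kidney and gonad (7.14 against 28.4), heart muscle (3.59 against 20.1) and skeletal muscle (4.56 against 25.1), each at percentile 0.01 or lower. They were also low in the pancreas (10.0003 against 25.9, percentile 0.63) and epidermis lists (6.52 against 21.7, percentile 0.815), and in lists of the gut and of pathways: endothelium (11.1 against 23.6, percentile 0.61), goblet and Paneth cells (11.8 against 26.5, percentile 1.81), mesenchyme (21.5 against 28.7, percentile 2.5), Wnt (25.1 against 34.2, below all random lists) and imprinted genes (18.8 against 31.7, percentile 0.14). With signal values of at least 5, the forebrain, kidney and gonad, heart, skeletal muscle and epidermis lists fell below the random range and the stomach list was within it. The heart, skeletal muscle and forebrain lists were below it at a −log10 q of at least 5 too, as were heart with a window of 500 bases (percentile 0.885) and heart (percentile 1.43), forebrain (percentile 2.07) and epidermis (percentile 2.445) with 1 TSS per gene. Of 1513 chemosensory receptor genes, 4 were marked, Olfr1033, Olfr658, Olfr94 and Vmn1r4, where random lists had a median of 59.

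Signalling pathway genes were marked throughout. All 12 hedgehog, 35 Wnt, 16 Notch and 20 BMP pathway genes were marked, the highest count each list could have, at percentiles 58.5, 89.6, 95.9 and 98.5. The hedgehog list had a median width of 3776.5 bases against 2112, above all random lists, with Ptch1 widest, Gas1 at 4816 ± 73.5 and Sufu at 4642 ± 156 bases. The median width was 2530 bases for Wnt genes, within the random range but above it in each single replicate and the replicated list, 2781.5 for Notch genes, at the edge of the random range, and 2778 for BMP genes (percentile 99.1). The Notch widths were within the random range at both thresholds, with 1 TSS per gene and in both whole-series lists. Without replicate 1 the Notch and BMP lists lay at the 94.4th and 90.7th percentiles. Wnt5a had 8482 ± 11.3 bases, Hes1 8412 ± 255 and Id2 8940 ± 98.3. Of 16 imprinted genes 15 were marked, with a median width of 3497.5 bases (percentile 99.98), and Ndn was unmarked. All 28 housekeeping and all 20 cell cycle genes were marked, with median widths of 2432.5 bases (percentile 98.8) and 2708 bases (percentile 99.9). The housekeeping widths were within the random range with signal values of at least 5 (percentile 91.8) and with 1 TSS per gene. The housekeeping genes had a median signal value of 38.8 against 31.4 (percentile 99.99).

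**Figure D3:**
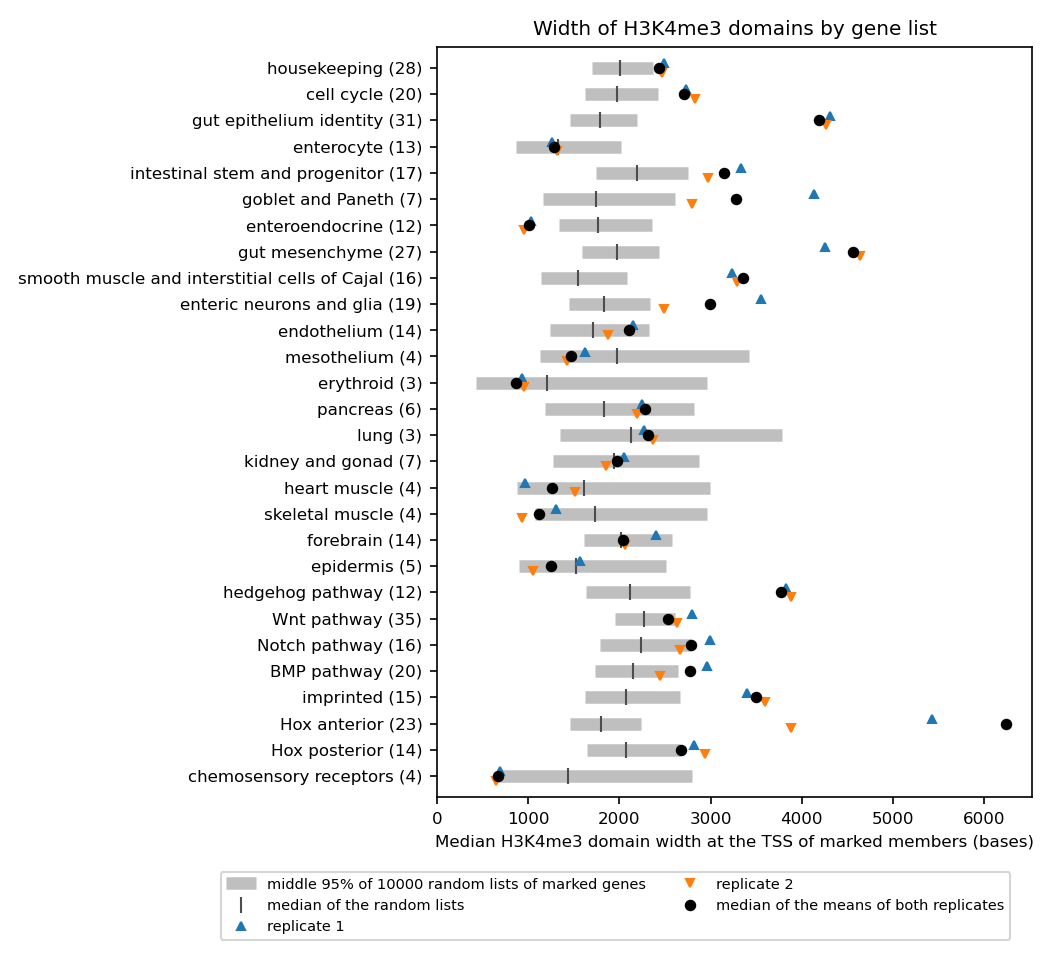
Median width in bases (x axis) of H3K4me3 domains at the TSS of the marked members of each list with at least 3 of them, with their number in brackets. Black circles are medians of the mean over both replicates, triangles the medians of single replicates, grey bars the middle 95% of 10000 random lists of marked genes and ticks their medians; epithelial identity (4183.5 bases) and mesenchyme (4557.5 bases) lie right of their bars.

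The Hox clusters were marked along their length, with higher median signal values in their anterior parts. All 23 anterior Hox genes, numbered 1 to 8, were marked (percentile 98.8). Of 16 posterior genes, numbered 9 to 13, 14 were marked (percentile 2.58), and Hoxc11 and Hoxd12 had a peak in replicate 2 only, so that 16 were marked without replicate 1 (percentile 64.1). The posterior count was below the random range without replicate 2, at a −log10 q of at least 5 and with a window of 500 bases. The median signal value was 19.7 for anterior genes and 7.57 for posterior genes, against random medians of 27.4 and 32.2. In the Hoxa cluster it was 20.7 for anterior and 8.50 for posterior genes, in Hoxb 20.3 and 7.76, in Hoxc 8.90 and 4.78, and in Hoxd 20.0 and 10.5. The 5′ ends of Hoxd3 and Hoxd4, and of anterior Hoxc5 and posterior Hoxc10, lay within 1000 bases of each other. A peak there can count for both genes, so the signal values are not all separate. Single genes departed from the higher anterior medians. Within 1000 bases of the 5′ end of Hoxb1 the highest signal values were 2.62 in replicate 1 and 3.10 in replicate 2. At the 5′ ends of Hoxa13 and Hoxd13 they were 14.8 and 11.7 in replicate 1 and 13.1 at both in replicate 2. Anterior genes had a median width of 6233 bases, above all random lists. It was 2312 bases without joining of peaks (percentile 99.98), 10915.5 with joining up to 3000 bases, and 3162.5 and 2869.5 at the q and signal thresholds. Taken within single replicates, the median was 5432 bases in replicate 1 and 3876 in replicate 2, as the joined domains differed between the replicates. Neighbouring genes such as Hoxb5 and Hoxb6 shared 1 joined domain, so the widths are not all separate values. Random lists drew genes from across the genome, so the width percentiles of the Hox lists can overstate the difference. The median width was 8381 bases for anterior and 5415.75 for posterior genes in Hoxa, 7597.25 and 2302.25 in Hoxb and 2645.25 and 1490.25 in Hoxc, but 2400.5 and 3664.25 in Hoxd. Posterior genes had a median width of 2671 bases (percentile 97.7). Without joining of peaks it fell to 1300.5 bases (percentile 0.03), and without replicate 1 it was at percentile 94.7. With signal values of at least 5, 9 posterior genes were marked, below all random lists, and 21 anterior genes, within the random range. The anterior list was also within it at a −log10 q of at least 5 (percentile 95.3), with 1 TSS per gene and in the pooled list, and the posterior widths at both thresholds, with 1 TSS per gene and in the replicated list.

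**Figure D4:**
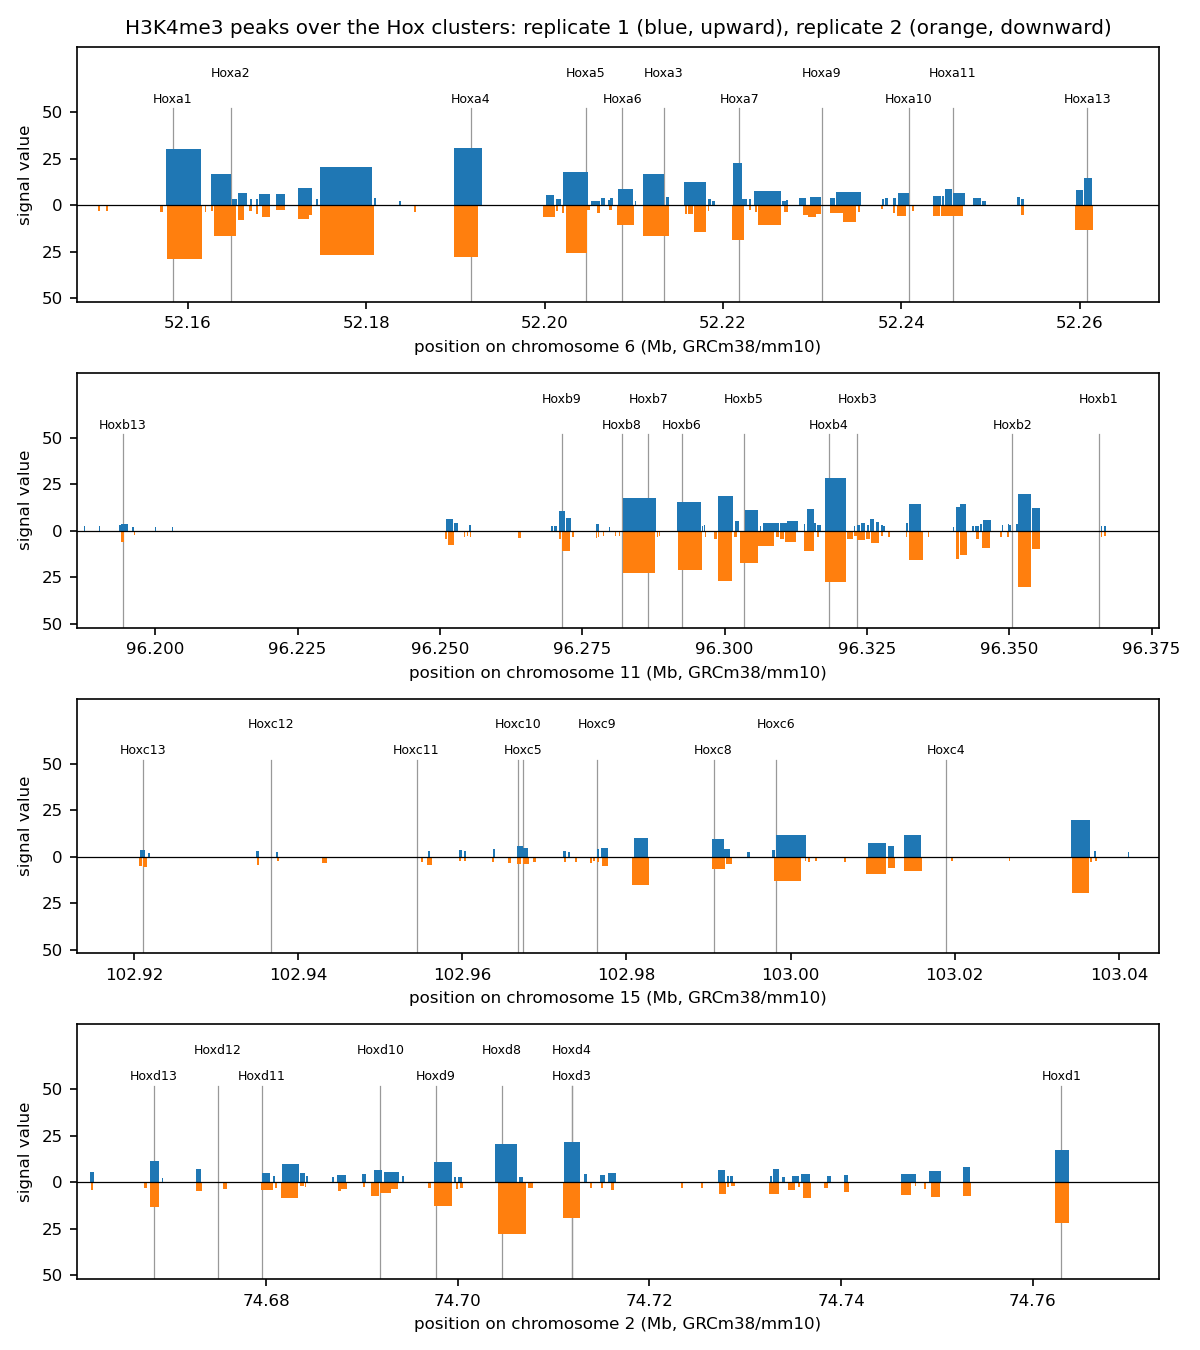
H3K4me3 peaks over the 4 Hox clusters, with the position in Mb (GRCm38/mm10) on the x axis and the signal value of each peak as bar height on the y axis, upward for replicate 1 and downward for replicate 2. Grey lines are the 5′ ends of the gene records; median signal values were 20.7 for anterior and 8.50 for posterior Hoxa genes.

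Genes marked in 1 replicate only numbered 179 in replicate 1 and 135 in replicate 2, with median signal values of 3.12 and 3.16. With a TSS window of 2000 bases, 56 of these 314 genes were marked in both replicates, among them 16 of the 19 with a signal value of at least 5. The strongest were Sdhaf1 (37.4), AC141477.1 (35.8), 1700017N19Rik (34.5), Tmem88b (21.2) and Aspdh (18.7) in replicate 1. In replicate 2 they were Exoc3l (45.5), Vpreb1 (31.9), Foxq1 (30.4), Tsks (19.5) and Tslp (10.6). The strongest 2 groups of peaks, which began at signal values of 15.4 in replicate 1 and 16.8 in replicate 2, were shared at 100%. Apart from that at Tslp, the peaks at these genes thus overlapped a peak of the other replicate that lay outside the TSS window. They were not peaks of 1 replicate only.

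Some strong peaks lay far from any annotated TSS. The strongest of the replicated list over 5000 bases away was on chromosome 8 from 69716123 to 69717072 (GRCm38/mm10), in no annotated gene and 5399 bases from the nearest TSS, that of Zfp869. Its signal value was 43.7 ± 0.964 over the replicates. The next lay on chromosome 9 from 67631757 to 67634693, 65488 bases from the pseudogene Gm47110, at 43.2 ± 7.61. The third lay on chromosome 11 from 74637421 to 74639482 inside Ccdc92b, at 37.9 ± 1.07. Of the strongest 10, 3 lay inside a gene, and their mean signal values ran from 32.7 to 43.7.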

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

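Peaks also lay on unplaced or unlocalised sequences, outside the assembled chromosomes. The comparisons of the report left these peaks out, and 1 alternative of the agreement between replicates included them. There were 14 such peaks in replicate 1 and 15 in replicate 2, on 7 sequences each. They are listed because they pass the limit of 3 that a count of 0 allows, which is no test, since nothing sets the number of peaks expected there. Their median signal values were 4.65 and 4.62, and the highest were 25.5 and 34.1. No explanation was tested.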

How the results depend on the processing

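Matching on start sites was chosen after seeing the data, and the other alternatives before. The number of marked genes, 14488, ran from 13766 with signal values of at least 5 to 14845 in the authors' pooled list. Every alternative run stayed within 1.5 times of it, a wide limit for a count out of 21853 genes. With 1 replicate left out the number was 14623 to 14667, and it could not fall, because 1 peak list then sufficed for a call. The count of lists wider than the random range, 14, stayed between 10 and 16, and was 12 to 15 with 1 replicate left out. Most shares of peaks moved by more than the SD they were set against, which was small. The shares found in the other replicate did not with all sequences (82.6% and 83.4%). Neither did the pooled share with overlap of 0.5 of the shorter peak (68.4%). For shares found in the other replicate, the SD was that of the 2 directions of 1 overlap, which does not measure variation between the pools. Replicate 1 peaks found in replicate 2 were 80.0% with overlap of 0.5 of the shorter peak, 71.2% with that of both peaks, 93.9% at a −log10 q of at least 5 and 96.5% at a signal value of at least 5. For replicate 2 these were 80.8%, 70.9%, 94.3% and 94.5%. Spearman's rho was 0.876, 0.940, 0.880 and 0.874, and 0.857 with all sequences. The Jaccard index was 0.847 and 0.851 with the stricter thresholds. Of the pooled list 62.1%, 81.9% and 93.3% were found in both replicates with overlap of both peaks, the q threshold and the signal threshold. Of the replicated list 94.0% were found with overlap of the shorter peak, 85.3% with that of both, 84.0% at the q threshold and 93.3% at the signal threshold.

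Peaks at a TSS were 61.1% and 75.5% with windows of 500 and 2000 bases, 80.3% and 85.6% at the q and signal thresholds and 61.4% with protein-coding TSSs only. Far peaks were 24.5% and 10.3% at distances of 2000 and 10000 bases, 10.9% and 8.48% at the thresholds and 22.3% with protein-coding TSSs. The 8 lists with more marked members than the random range became 5 at the q threshold, 3 at the signal threshold and 13 without matching. The 5 lists with fewer became 10, 11 and 10, and 8 with 1 TSS per gene. The 1 list with narrower domains became 2 at the q threshold, 2 with 1 TSS per gene, 2 with either replicate left out, 3 and 2 in the replicated and pooled lists, 5 without matching and 8 without joining. Apart from what each alternative counts by construction, the cause was not tested. Of single lists, 26 of 297 counts of marked members moved by over 1.5 times and 145 of 245 median widths moved by more than the spread. Of 328 named genes, 31 changed their call at the signal threshold and 12 with either replicate left out. No paired analysis was possible because the series has 1 group. Depth is unknown, so weak peaks cannot be tied to it.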

Other observations

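The tests of cells of other organs, of the far peaks' sharing, and of joining in the smooth muscle, enteric neuron and posterior Hox lists were chosen after the result was seen, as was matching on start sites. No biological explanation by a difference between groups was tested, since the series has 1 group.

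The 4 non-coding members of the imprinted list carried H3K4me3 at a TSS in both replicates. H19 had a domain of 3438 ± 462 bases, Kcnq1ot1 3289.5 ± 211, Meg3 3092.5 ± 26.2 and Airn 2253.5 ± 207 bases, at signal values of 14.6 ± 0.776, 17.5 ± 2.36, 17.2 ± 0.10 and 17.5 ± 3.26.

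Wide domains were found at 12 lists besides the Hox genes. Without joining of peaks 10 of the 12 stayed above the random range, as did the anterior Hox list at percentile 99.98, which argues against joining as the whole cause there. Joining still made up most of the anterior Hox width, whose median was 2312 bases against 1608 in random lists without joining and 6233 against 1798.5 with it. For smooth muscle and enteric neurons (percentile 71.9 at most) and for posterior Hox genes (0.03th), joining of several narrower peaks is a candidate explanation. Random lists were then matched on broader CpG classes and on broad classes of the number of annotated start sites within 5000 bases. All 12 of the 12 stayed above the range, housekeeping only just (percentile 97.56). This argues against crowded start sites, as counted in such broad classes, as the whole cause for these lists. Random medians moved little here too, for example from 1782.5 to 1724 bases for epithelial identity and from 2111.75 to 1956.25 for hedgehog. Crowding on a finer scale thus stays open. The anterior Hox list stayed at percentile 100, but its random median hardly moved, from 1798.5 to 1814 bases. Such broad classes may not match clustered Hox genes, whose joined domains can span several genes. Crowding there stays open. CpG counts were matched only within 500 bases of a TSS, less than the widths compared. Whether width follows CpG content further out, expression or cell number was not tested.

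Of 144 genes of 11 lists of other organs, 49 were marked, at a median signal value of 7.83 against 28.6 in random lists. Of these 49 genes 41 (83.7%) stayed marked at a −log10 q of at least 5, against 14110 of all 14488 marked genes. Only 32 of the 49 had signal values of at least 5, against 13766 of 14488. Most of the 49 thus kept the call, which argues against peaks near the calling threshold for the genes that stayed. A low signal value and a peak near the threshold are closely tied, so these counts cannot part them as causes. The 49 genes still lost the call more often than marked genes in general, so peaks near the threshold stay open as part of the cause. Of the other-organ members with CpG-rich promoters 38 of 49 were marked, below all random lists (median 48, middle 95% from 45 to 49). Among members with CpG-poor promoters, the lower 4 deciles, 11 of 95 were marked. That was also below all random lists (median 26, middle 95% from 19 to 34). Such random lists also hold genes active in the gut, so this count cannot exclude cells of those organs in the dissected tissue, which stay open. The 11 genes were Actn3 (42.1), Rbpjl (10.5), Sfn (7.41), Bhlha15 (6.38), Opn1sw (4.998), Pax8 (4.92), Ttr (4.67), Nphs1 (3.81), Tnni3 (3.62), Myl7 (3.56) and Tbr1 (2.91). Actn3 lay far above the others, and such a peak can belong to a neighbouring gene, which was not examined for these genes. Some members may be silent in their own organ at this age, and neither expression nor another histone mark was analysed here.

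Of the peaks far from annotated start sites, 66.1% in replicate 1 and 66.7% in replicate 2 were found in the other, against 82.6% and 83.4% of all peaks and 0.262% and 0.269% of peaks shuffled to far places. This argues against noise that falls independently in each replicate as the whole cause. It leaves open the far peaks of 1 replicate only and artefacts common to both. Signal values were at least 5 in both replicates for 1275 far peaks. Their sequence was CpG-dense, with a median of 39.7 CpG per kilobase against 49.1 in peaks at a TSS and 5.96 in shuffled peaks, consistent with CpG-dense sequence as a source. A RefSeq transcript start lay within 1000 bases of 20.7% of them, against 1.43% of shuffled peaks. For the rest, start sites missing from both annotations and other elements cannot be told apart, because no transcript data were analysed.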
